A study of Rattus norvegicus with 30 samples.

How the data were processed

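Gene expression was measured in ileum from 30 male Long-Evans rats aged 8 to 10 weeks, with 1 array per rat and 6 rats in each of 5 groups. The groups were Roux-en-Y gastric bypass (RYGB), the sham operation for it (Sham_RYGB), vertical sleeve gastrectomy (VSG), the sham operation for it (Sham_VSG), and that sham operation with paired feeding (Sham_VSG_PF). In VSG about 80% of the stomach was transected. The series description also speaks of duodenum, which was not analysed here. Total RNA was amplified with the Ovation PicoSL WTA system, labelled with biotin and hybridized to 1-colour Affymetrix arrays. The deposited values are log2 signals that the authors computed with RMA in Affymetrix Expression Console 1.3.0.187, which corrects background, quantile normalizes the probes and gives 1 value per transcript cluster. Which arrays were normalized together is not stated, and no scan dates, detection calls or scanner files were used.

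The table held 36685 transcript clusters, of which 14824 carried exactly 1 gene symbol, 829 carried several and 21032 were not named. For each of the 14557 distinct symbols the cluster with the highest mean over the 30 arrays was kept. Genes with a mean below the 25th percentile of these (a log2 value of 2.33) were left out, and 10918 genes were tested. Slc11a2, Hif1a and Cck had no cluster named for them alone and gave no value. The median log2 value per array ran from 3.10 to 3.25, and the correlation between any pair of arrays from 0.934 to 0.987. For arrays the number of rats limits the precision: the median 95% confidence interval of a log2 fold change reached 0.31 to either side.

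A linear model with a mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and 25 residual degrees of freedom. The contrasts were RYGB against Sham_RYGB, VSG against Sham_VSG, VSG against Sham_VSG_PF, Sham_VSG_PF against Sham_VSG, Sham_RYGB against Sham_VSG, and the RYGB effect minus the VSG effect, each taken against its own shams. P-values are two-sided and were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Means are given with the SD over the 6 rats of a group. Folds are powers of the difference of the log2 means. Tests on single values enumerated all splits of the 12 arrays compared, as exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

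Before the data were examined, 33 gene lists were fixed: iron absorption and handling, hypoxia and HIF, gut hormones and enteroendocrine cells, bile acid transport and FXR, cholesterol synthesis and SREBP2, lipid absorption and chylomicrons, fatty acid oxidation and PPAR-alpha, sugar digestion and absorption, peptide and amino acid absorption, stem cells and Wnt, proliferation, goblet cells, Paneth cells, epithelial defence, tuft cells, T and NK cells, B and plasma cells, macrophages and dendritic cells, mast cells and eosinophils, MHC class II, interferon response, smooth muscle, enteric neurons and glia, fibroblasts and matrix, pancreatic acinar cells, fat cells, red blood cells, xenobiotic and glutathione, unfolded protein and integrated stress response, circadian clock, immediate early genes, proximal small intestine, and posterior Hox genes. Each was tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes, and adjusted over the 33 lists of a contrast. Listed symbols without a tested gene were left out, and counts of members refer to those tested. These were 4 of 18 for acinar, 8 of 15 for sugar, 9 of 18 for stem cell, 9 of 16 for smooth muscle and 12 of 19 for tuft cell genes, among others. Camera with an estimated correlation, and fry, which tests whether a list's genes move one way without comparing them with other genes, were run as alternatives.

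The genes named were also set by a rule fixed before the data were examined. Per contrast, the rule took the 10 genes with the largest positive and the 10 with the largest negative change among those past the threshold, or, where none passed, the 10 with the smallest p. From each list it took up to 4 members past the threshold, or the 2 with the smallest p where the list passed with fewer than 2 such members. In the RYGB and VSG contrasts against shams it also took Slc11a2, Cybrd1, Slc40a1, Heph, Tfrc, Epas1, Hif1a, Gcg, Pyy, Nts and Cck.

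Alternatives fixed beforehand were quantile normalization over the 30 arrays, centring each array on its median, no filter on dim genes or a filter at the 50th percentile, fits of only the groups compared, the replicate number as a block, array quality weights, a variance trend with robust moderation, the mean of a gene's clusters, the mean of the smooth muscle list or of the B and plasma cell list as a covariate, an adjusted p below 0.10, a change of at least 1.5 times, and leaving out each array in turn. Alternatives chosen after seeing the data were the mean of the fat cell list as a covariate, only arrays low in B cell genes, leaving out arrays high in fat cell genes, and testing all transcript clusters, named or not. Replicate numbers are shared between groups, but the labels do not say that they pair rats. The rats were treated as unpaired.

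The procedure was tested on simulated data with the spread of these arrays and independent genes. In the RYGB contrast 43.6% of genes changed by a log2 value of 0.5 were recovered, 88.5% at 1 and 94.8% at 1.5, with 5.4% false calls on average. Each simulation changed 50 genes at each of the log2 values 0.5, 1, 1.5 and 2 at once, which eases the adjusted threshold. These shares therefore do not give the chance of finding such a change in contrasts where few or no genes passed.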

Results

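The values are log2 signals from ileum of 30 rats, 6 in each of 5 groups: gastric bypass (RYGB), its sham operation (Sham_RYGB), sleeve gastrectomy (VSG), its sham operation (Sham_VSG), and that sham operation with paired feeding (Sham_VSG_PF). The arrays' median log2 values lay between 3.10 and 3.25. The strongest difference between arrays was in lymphoid genes: the first principal component held 40.3% of the variance and its correlation with the mean of the B and plasma cell list was 0.988. That mean fell into 2 separate ranges, 4.01 to 4.81 in 19 arrays and 6.74 to 8.07 in 11 arrays. The upper range held 1 RYGB, 3 Sham_RYGB, 2 VSG, 3 Sham_VSG and 2 Sham_VSG_PF arrays. Fat cell genes were high in 4 arrays (list means of 6.19 to 7.09), which were 3 RYGB arrays and 1 VSG array, and lay between 3.88 and 4.63 in the other 26. No sham array of the 18 was in the high set.

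**Figure D1:**
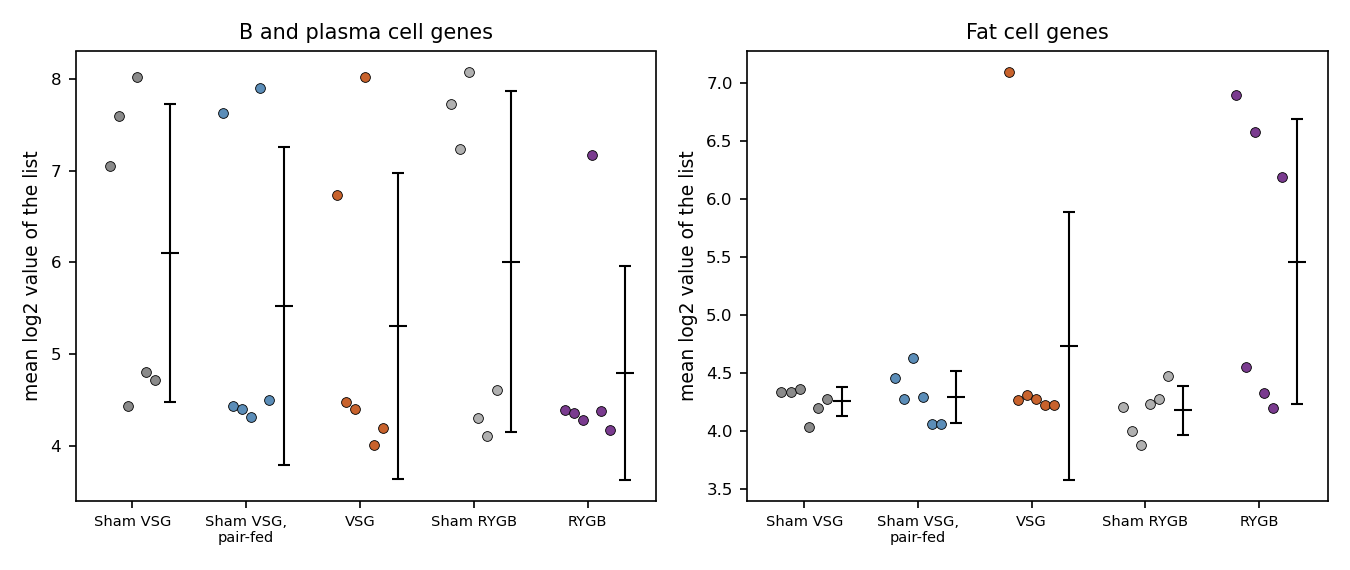
Mean log2 value of the B and plasma cell list and of the fat cell list in each of the 30 arrays, by group, with the group mean and SD (n = 6). The B and plasma cell values fall into a lower set of 19 and an upper set of 11 arrays, and 4 arrays of operated rats lie between 6.19 and 7.09 for fat cell genes.

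The comparison of RYGB with Sham_RYGB asked what the bypass changed in the ileum. The series concerns the gut's iron uptake genes and its hormones. The transferrin receptor gene Tfrc, through which cells take up iron bound to transferrin, rose 1.76-fold, from 7.97 ± 0.19 to 8.79 ± 0.37 (SD, n = 6; adjusted p = 0.023). Cidec, a protein of lipid droplets, was 3.25-fold higher (7.97 ± 0.43 against 6.27 ± 0.62; adjusted p = 0.00111). Cpt1a, which admits fatty acids to mitochondria for oxidation, was 1.54-fold higher (7.45 ± 0.24 against 6.83 ± 0.19; adjusted p = 0.0285). The peptidase gene Lap3 rose 1.79-fold (9.95 ± 0.21 against 9.11 ± 0.18; adjusted p = 0.000687). Ace, another peptidase gene, rose 2.44-fold (9.09 ± 0.48 against 7.80 ± 0.60; adjusted p = 0.0348). Alox5, the enzyme that starts leukotriene synthesis and a member of the tuft cell list, was 1.72-fold lower (4.76 ± 0.35 against 5.54 ± 0.34; adjusted p = 0.0348). These genes moved alongside higher fat cell and lower B and plasma cell genes in the same arrays (list means of 5.45 ± 1.23 against 4.18 ± 0.21, and of 4.79 ± 1.17 against 6.01 ± 1.85).

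In all, 20 of 10918 genes passed, 17 higher and 3 lower. Another count, of genes with an unadjusted p under 0.05, was 1414, and 5 of 100 regroupings of the arrays gave as many. Areg, a ligand of the EGF receptor, was 2.64-fold higher and Cdr2 2.17-fold higher (both with adjusted p = 0.023). Aqp3, a channel for water and glycerol, was 1.99-fold higher (adjusted p = 0.0313). Prr15 was 1.91-fold higher (adjusted p = 0.0235), and Gimd1 and the mitochondrial carrier Slc25a34 were both 1.78-fold higher (adjusted p = 0.023 and 0.0234). Poc5 was 1.66-fold lower (adjusted p = 0.0237). Ptprz1 was lower, at 2.23 ± 0.16 against 2.70 ± 0.15 (adjusted p = 0.0348), and no fold is given, since the RYGB mean lay below the level of the filter on dim genes, 2.33, and the data hold no detection calls. Each of these 14 genes lay on the same side of the sham mean in 6 of 6 RYGB arrays. The remaining 6, named here outside the rule, were Acsl3, Tmem150b, Lpgat1, Sec22b, Tnfrsf1a and Vmp1, higher by log2 values of 0.42 to 0.59.

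**Figure D2:**
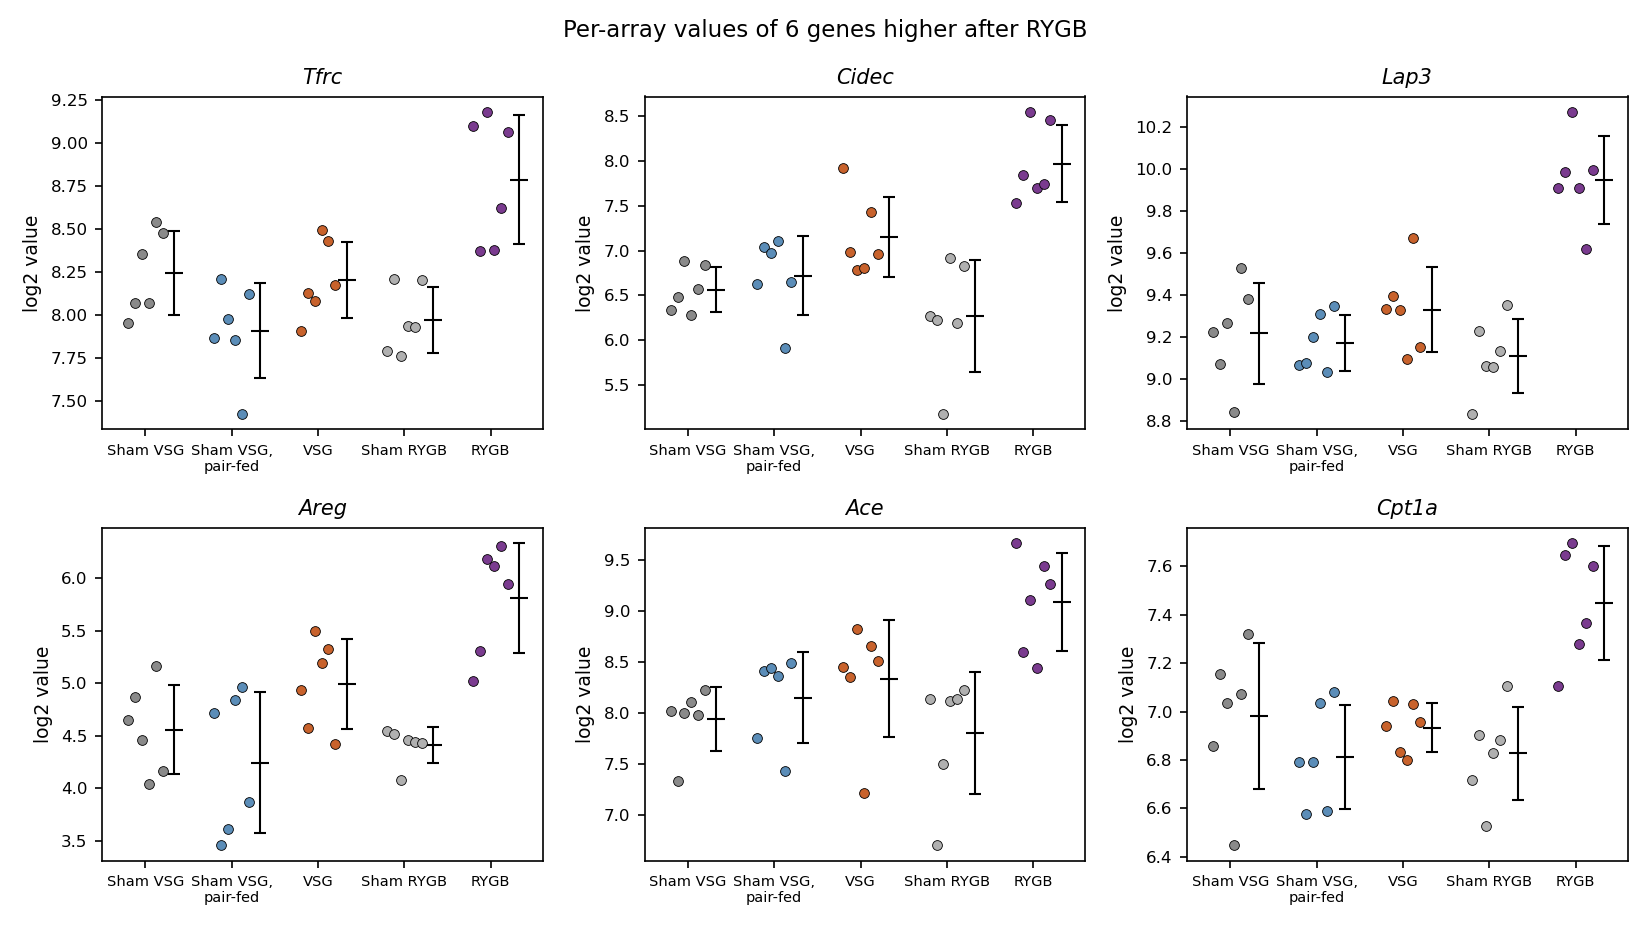
Log2 values of Tfrc, Cidec, Lap3, Areg, Ace and Cpt1a in each array, by group, with the group mean and SD (n = 6). All 6 passed the threshold in RYGB against Sham_RYGB, and the 6 RYGB arrays lie above the Sham_RYGB mean for each.

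The number of genes past the threshold depended on the arrays and the model. A fit of the RYGB and Sham_RYGB arrays alone gave 0 (lowest adjusted p = 0.0622, and all 20 genes with an unadjusted p under 0.05), and a smooth muscle covariate gave 67. Alternatives chosen after the data were seen were a fat cell covariate, which gave 1 (Lap3), and all transcript clusters, which gave 3. Only the arrays low in B cell genes gave 8, of which 7 were among the 20. All 20 had the same sign there and kept a median 0.924 and at least 0.745 of their log2 fold change. Without the arrays high in fat cell genes 1 gene passed, C1h11orf24, which was not among the 20. By limma 0 of the 20 passed there, with all 20 at an unadjusted p under 0.05 and of the same sign. They kept a median 0.942 and at least 0.597 of their log2 fold change, the least being Tfrc, at 0.49 in place of 0.82. Leaving out 1 array gave 2 (RYGB replicate 6), 3 (Sham_RYGB replicate 3), 8 (Sham_RYGB replicate 2), 10 (RYGB replicate 2), 12 (Sham_RYGB replicate 1) or 41 (RYGB replicate 4). Lap3 and Cidec passed with each of the 12 arrays left out in turn. Tfrc did not pass without RYGB replicate 6 or Sham_RYGB replicate 3 (adjusted p = 0.0782 and 0.0854). The other 11 of the 14 genes did not pass in 2 to 8 of the 12 cases, with a highest adjusted p of 0.134 for Alox5 without Sham_RYGB replicate 1.

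Apart from Tfrc, no iron gene passed after RYGB. The iron list had 12 of 16 measured members higher and 4 lower. Of these, 1 passed over all genes and 1 when adjusted over the list alone. The list did not pass (camera adjusted p = 0.0836, and adjusted p = 0.166 with an estimated correlation). It passed by fry (adjusted p = 0.0214) and with a B and plasma cell covariate (adjusted p = 0.0113). The iron exporter gene Slc40a1 (ferroportin) was at 5.06 ± 0.66 against 4.61 ± 0.19 (adjusted p = 0.345), a log2 difference of 0.46 that was 0.20 without RYGB replicate 5. Its partner oxidase Heph was at 8.08 ± 0.20 against 7.67 ± 0.23 (adjusted p = 0.294). The brush border reductase Cybrd1 was at 7.14 ± 0.98 against 7.07 ± 0.42 (adjusted p = 0.931), a difference of 0.07 that was -0.31 without the same array and 0.23 without RYGB replicate 3. In the iron list 4 genes had 95% intervals without 0, namely Tfrc, Heph and Slc40a1, which were higher, and Tf, which was lower. Epas1, the HIF subunit that drives iron uptake genes in the gut, was at 7.71 ± 0.20 against 7.62 ± 0.32 (adjusted p = 0.814), a difference of 0.09 that was 0.01 without Sham_RYGB replicate 2 and 0.16 without Sham_RYGB replicate 1.

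None of the measured hormone genes passed after RYGB. Pyy was at 9.82 ± 0.19 against 9.46 ± 0.22, and Nts at 8.94 ± 0.36 against 8.54 ± 0.72 (adjusted p = 0.270 and 0.533). The Nts difference of 0.41 was 0.18 without Sham_RYGB replicate 3. Gcg, the precursor of GLP-1, was at 9.39 ± 0.33 against 9.16 ± 0.37 (adjusted p = 0.589), a difference of 0.23 that was 0.11 without Sham_RYGB replicate 3 and 0.13 without RYGB replicate 6. The hypoxia list had 12 of 20 members higher (camera adjusted p = 0.108) and the hormone list 10 of 17 (camera adjusted p = 0.657). In both, 0 members passed over all genes and 0 adjusted over the list alone, while 5 hypoxia and 2 hormone genes had 95% intervals without 0.

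**Figure D3:**
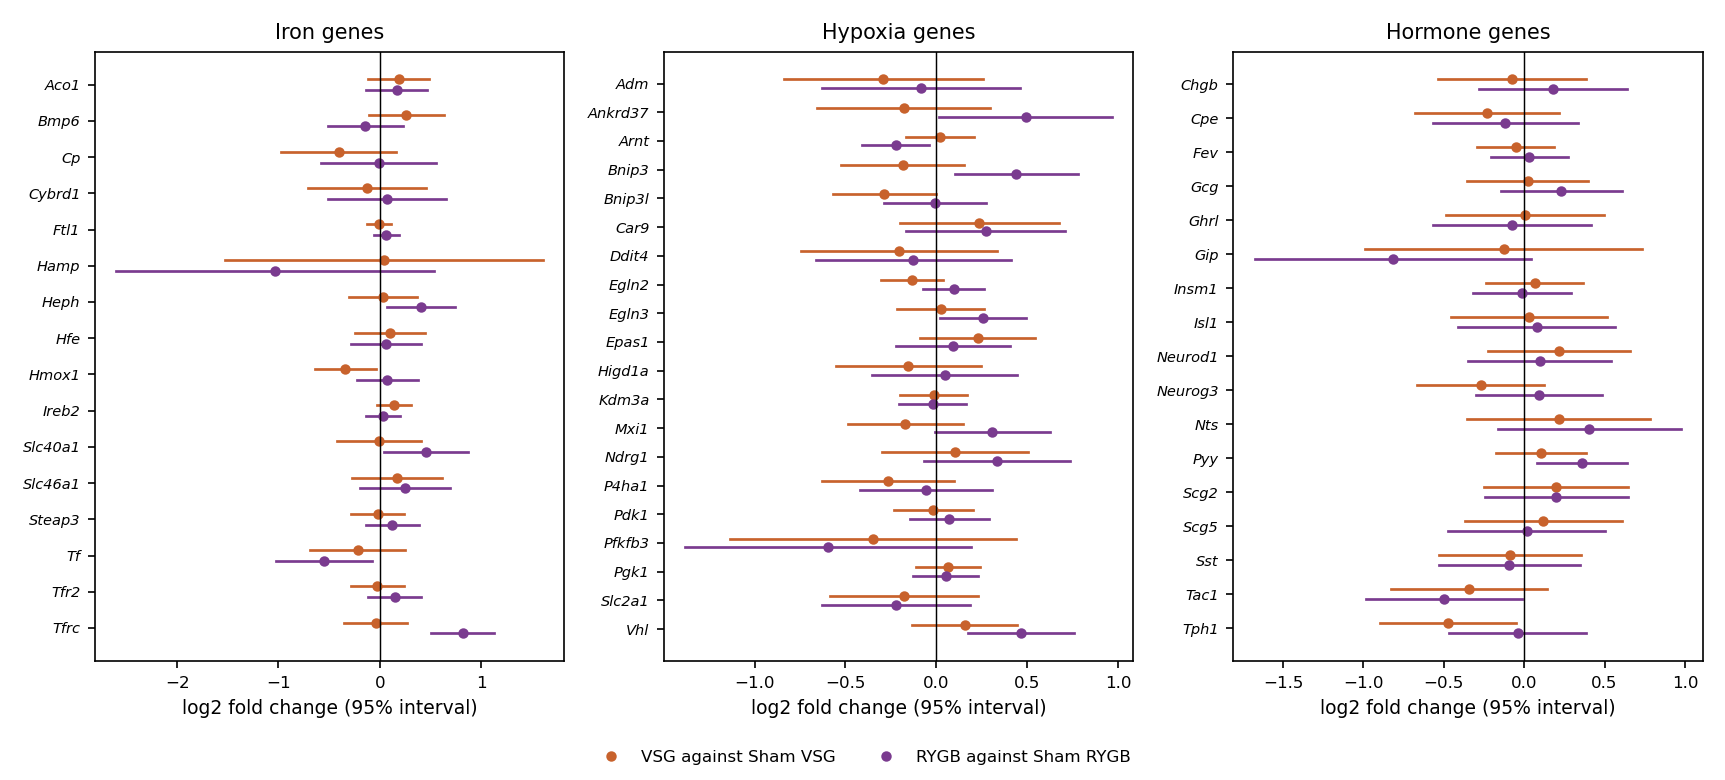
Log2 fold changes with 95% confidence intervals for the measured genes of the iron, hypoxia and hormone lists after VSG and after RYGB, each against its own shams (n = 6 per group). Tfrc after RYGB (0.82) is the 1 gene past the threshold among them.

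After RYGB 12 lists passed by camera at the preset correlation, and 0 with an estimated one. In the lipid absorption list 18 of 20 members were higher, 0 past the threshold over all genes and 12 when adjusted over the list alone. Its camera adjusted p was 5.37e-09, and it had adjusted p = 0.166 with an estimated correlation. Its members included Creb3l3, a regulator of lipoprotein genes, at 9.06 ± 0.35 against 7.89 ± 0.65 (adjusted p = 0.0706). Apoc2 was at 10.20 ± 0.28 against 9.60 ± 0.24 (adjusted p = 0.0807). In the fatty acid oxidation list 19 of 22 were higher, 1 past the threshold and 9 adjusted over the list alone. This list's camera adjusted p was 5.78e-09, and it had adjusted p = 0.166 with an estimated correlation. Pdk4, which spares glucose when fat is burned, was at 7.34 ± 0.92 against 5.56 ± 0.79 (adjusted p = 0.0833). Fat cell genes, Cidec among them, were higher in 8 of 8 members, 1 past the threshold and 6 adjusted over the list alone. Their camera adjusted p was 2.06e-07, and they had adjusted p = 0.166 with an estimated correlation. Car3, from that list, was at 5.84 ± 2.94 against 3.18 ± 0.30 (adjusted p = 0.235).

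Peptide and amino acid genes were higher after RYGB in 14 of 14 members, 1 past the threshold and 2 adjusted over the list alone. For peptide genes camera gave adjusted p = 7e-06, and adjusted p = 0.232 with an estimated correlation. The list held Ace and the enteropeptidase gene Tmprss15, at 3.64 ± 1.53 against 1.93 ± 0.31 (adjusted p = 0.0814). Sugar genes were higher in 8 of 8, 0 past the threshold and 2 adjusted over the list alone. For sugar genes camera gave adjusted p = 0.00682, and adjusted p = 0.354 with an estimated correlation. Pck1 was at 8.14 ± 0.61 against 6.28 ± 1.09, and Treh at 4.99 ± 0.37 against 4.29 ± 0.43 (adjusted p = 0.128 and 0.197). Genes typical of the proximal small intestine were higher in 8 of 9, 0 past the threshold and 3 adjusted over the list alone. For proximal genes camera gave adjusted p = 0.00682, and adjusted p = 0.166 with an estimated correlation. Ada was at 9.98 ± 0.31 against 9.35 ± 0.53, and Apoa4 at 11.47 ± 0.24 against 10.63 ± 0.87 (adjusted p = 0.138 and 0.165). Without Sham_RYGB replicate 3 the Apoa4 difference of 0.85 was 0.52.

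Immediate early genes, which respond to stimuli within minutes, were higher after RYGB in 12 of 14, 0 past the threshold and 5 adjusted over the list alone. Camera gave adjusted p = 9.7e-05, and adjusted p = 0.0892 with an estimated correlation. Among them Dusp1 was at 7.12 ± 0.31 against 6.28 ± 0.49, and Jun at 7.87 ± 0.28 against 7.42 ± 0.29 (adjusted p = 0.0807 and 0.138).

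Tuft cell genes, which mark a chemosensory epithelial cell, were lower after RYGB in 12 of 12 members, 1 past the threshold and 8 adjusted over the list alone. For tuft cells camera gave adjusted p = 7e-06, and adjusted p = 0.166 with an estimated correlation. The tuft cell regulator Pou2f3 was at 4.52 ± 0.67 against 5.41 ± 0.43 (adjusted p = 0.138). Its log2 difference of -0.89 was -0.34 without the arrays high in fat cell genes. Goblet cell genes were higher in 12 of 13, 0 past the threshold and 0 adjusted over the list alone. For goblet cells camera gave adjusted p = 0.0018, and adjusted p = 0.281 with an estimated correlation. The mucus genes Fcgbp and Spink4 were at 10.65 ± 0.09 against 10.39 ± 0.13 and at 10.46 ± 0.46 against 9.83 ± 0.56 (adjusted p = 0.251 and 0.357). Proliferation genes were lower in 24 of 24, 0 past the threshold and 0 adjusted over the list alone. For proliferation camera gave adjusted p = 8.87e-09, and adjusted p = 0.232 with an estimated correlation. Cdk1 was at 6.28 ± 0.25 against 6.72 ± 0.23, and Pcna at 8.45 ± 0.23 against 8.79 ± 0.18 (adjusted p = 0.220 and 0.231).

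B and plasma cell genes were lower after RYGB in 16 of 16 members, and macrophage and dendritic cell genes in 16 of 18. In both lists 0 members passed over all genes and 0 adjusted over the list alone. For B and plasma cells camera gave adjusted p = 0.00332, and adjusted p = 0.596 with an estimated correlation. For macrophages camera gave adjusted p = 0.00648, and adjusted p = 0.563 with an estimated correlation. Pou2af1 was at 4.42 ± 1.28 against 5.76 ± 1.73, and Cd180 at 3.11 ± 1.75 against 5.01 ± 2.68 (adjusted p = 0.516 and 0.517). Ccr2 was at 3.69 ± 0.35 against 4.54 ± 0.85, and Ccl2 at 5.89 ± 0.93 against 6.65 ± 0.76 (adjusted p = 0.277 and 0.371). Without RYGB replicate 2 the Ccl2 difference of -0.76 was -0.40. T and NK cell genes, lower in 14 of 20, did not pass (camera adjusted p = 0.0841). The sugar and the B and plasma cell lists did not pass without Sham_RYGB replicate 3 (adjusted p = 0.0700 and 0.0658), nor the macrophage list without RYGB replicate 2 (adjusted p = 0.0687). The other 9 lists passed by camera with each array left out in turn. In the 16 other alternatives, part of them chosen after the data were seen, the call was lost in 4 each for sugar, proximal and macrophage genes (adjusted p of at most 0.354, 0.232 and 0.742). It was lost or turned in 5 for B and plasma cell genes and 3 for fat cell genes (at most 0.907 and 0.798), and lost in 1 or 2 for each of the other 7 lists (at most 0.281). Without the arrays high in fat cell genes the fat cell and the B and plasma cell lists did not pass (adjusted p = 0.194 and 0.146). With a B and plasma cell covariate the sugar and macrophage lists did not pass by camera (adjusted p = 0.0973 and 0.742), nor with only the arrays low in B cell genes (0.232 and 0.581). By fry 6 lists passed, namely iron, lipid absorption, fatty acid oxidation, fat cells, tuft cells and immediate early genes (lowest adjusted p = 0.00629).

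**Figure D4:**
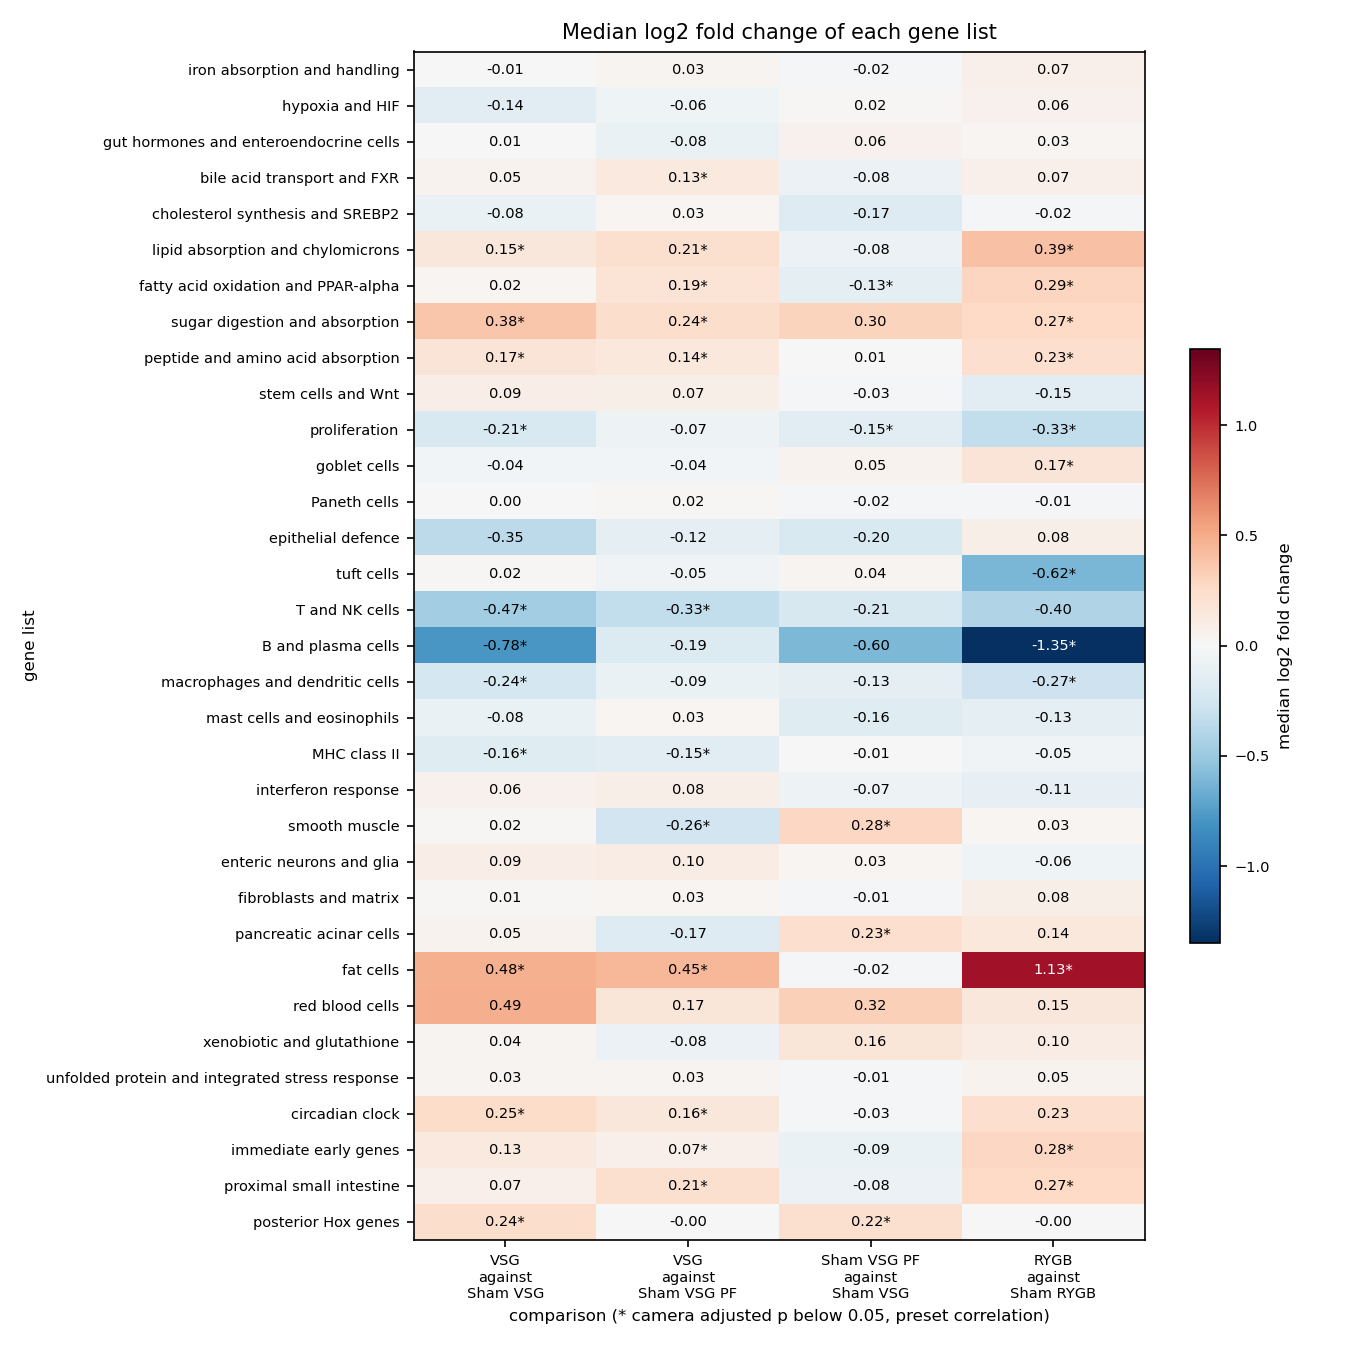
Median log2 fold change of each of the 33 gene lists in 4 comparisons (n = 6 per group), with an asterisk where camera's adjusted p at the preset correlation was below 0.05. With an estimated correlation 0 lists passed in any comparison; the lowest adjusted p was 0.0892, for immediate early genes after RYGB.

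The comparison of VSG with Sham_VSG asked what the sleeve operation, which acts on the stomach, changed in the ileum. S100g, the calcium-binding protein calbindin-D9k of absorptive cells, was at 10.54 ± 0.55 against 8.80 ± 0.54. It was 3.35-fold higher, above the sham mean in 6 of 6 arrays, and did not pass (adjusted p = 0.605). No iron gene passed, and 1 of the 16 had a 95% interval without 0, Hmox1, with a log2 difference of -0.34 (interval -0.64 to -0.04; adjusted p = 0.788). Tfrc was at 8.20 ± 0.22 against 8.24 ± 0.25, and Slc40a1 at 4.67 ± 0.19 against 4.68 ± 0.20 (adjusted p = 0.965 and 0.994). Heph was at 7.83 ± 0.38 against 7.80 ± 0.29, and Cybrd1 at 6.99 ± 0.27 against 7.12 ± 0.19 (adjusted p = 0.977 and 0.929). Epas1 was at 7.71 ± 0.23 against 7.48 ± 0.39 (adjusted p = 0.843), a difference of 0.23 that was 0.14 without Sham_VSG replicate 2 or 5. The Cybrd1 difference of -0.13 was -0.05 without VSG replicate 2. With 1 array left out in turn the differences of Heph, Tfrc and Slc40a1 lay between -0.10 (Tfrc without Sham_VSG replicate 1) and 0.17 (Heph without VSG replicate 4). The hormone genes Gcg, Pyy and Nts were at 9.42 ± 0.36 against 9.39 ± 0.21, 9.45 ± 0.28 against 9.35 ± 0.17, and 8.73 ± 0.61 against 8.51 ± 0.31 (adjusted p = 0.984, 0.899 and 0.899). The Nts difference of 0.21 was 0.05 without VSG replicate 1, 0.13 without VSG replicate 3 and 0.37 without VSG replicate 4. For Pyy the difference of 0.10 was 0.02 without VSG replicate 3, 0.04 without Sham_VSG replicate 4 and 0.18 without VSG replicate 4. Gcg's, of 0.02, lay between -0.08 (without VSG replicate 6) and 0.09 (without VSG replicate 5).

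With limma 0 genes passed after VSG, and the lowest adjusted p was 0.183. There were 661 genes with an unadjusted p under 0.05, and 15 of 100 regroupings of the arrays gave as many. Besides S100g, the genes with the smallest p included Andpro, Anks3, Rpl30 and Uts2r, with log2 differences of 0.98, 0.51, 0.51 and 0.41. S100a11l2, Tmem80, Fam185a, Nqo1 and Cxcl6 had log2 differences of -1.02, -0.83, -0.45, -0.87 and -0.84. The iron list had 7 members higher and 9 lower (camera adjusted p = 0.649). The hypoxia list had 7 higher and 13 lower (camera adjusted p = 0.504), and the hormone list 9 higher and 8 lower (camera adjusted p = 0.960). In these 3 lists 0 members passed adjusted over the list alone.

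By camera 11 lists passed after VSG, each with 0 members past the threshold over all genes and 0 adjusted over the list alone. Sugar genes were higher in 8 of 8 members and peptide and amino acid genes in 13 of 14 (camera adjusted p = 0.000779 for both). Both had adjusted p = 0.574 with an estimated correlation. The glucose transporter Slc5a1 was at 9.76 ± 0.22 against 9.38 ± 0.58, and Lct at 4.11 ± 0.75 against 3.60 ± 0.28 (both with adjusted p = 0.828). The Slc5a1 difference of 0.38 was 0.17 without Sham_VSG replicate 2, and the Lct difference of 0.51 was 0.27 without VSG replicate 1. Slc3a2 and Slc3a1, of amino acid transporters, had log2 differences of 0.17 and 0.21, which were 0.11 without VSG replicate 3 and 0.14 without VSG replicate 5 or Sham_VSG replicate 2. Lipid absorption genes were higher in 14 of 20 (camera adjusted p = 0.00894). That list had adjusted p = 0.637 with an estimated correlation. Abcg5 was at 6.48 ± 0.92 against 5.49 ± 0.94, and Dgat2 at 7.74 ± 0.34 against 7.42 ± 0.28 (both with adjusted p = 0.828).

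Clock genes were higher after VSG in 9 of 11 members and posterior Hox genes in 8 of 9 (camera adjusted p = 0.00806 and 0.019). Each had adjusted p = 0.574 with an estimated correlation. Per1 and Per2 had log2 differences of 0.47 and 0.68, and Hoxa7 and Hoxc9 of 0.35 and 0.26. The posterior Hox means lay between 4.21 and 4.54 in the 11 arrays high in B and plasma cell genes and between 4.57 and 5.07 in the other 19. With a B and plasma cell covariate the Hox list did not pass (adjusted p = 0.320), and with only the arrays low in these genes it did (adjusted p = 0.00657). Fat cell genes were higher in 8 of 8 (camera adjusted p = 0.00532), with list means of 4.73 ± 1.16 against 4.26 ± 0.13. That list had adjusted p = 0.574 with an estimated correlation, and Cidec and Retn had log2 differences of 0.59 and 0.55. The fat cell difference rests on VSG replicate 1, whose list mean was 7.09 where those of the other 5 VSG arrays lay between 4.22 and 4.31. Without it the list did not pass (adjusted p = 0.665), and Retn's difference was 0.20.

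Proliferation genes were lower after VSG in 24 of 24 members (camera adjusted p = 0.000494). They had adjusted p = 0.574 with an estimated correlation, and Bub1b and Plk1 had log2 differences of -0.41 and -0.32. T and NK cell genes were lower in 20 of 20 and macrophage genes in 17 of 18 (camera adjusted p = 0.00532 for both). The former had adjusted p = 0.657 with an estimated correlation and the latter adjusted p = 0.637 with an estimated correlation. Prf1 and Cd247 had log2 differences of -0.80 and -0.72, and Adgre1 and Cd14 of -0.60 and -0.34. Without VSG replicate 3 the Prf1 difference was -0.46. MHC class II genes were lower in 9 of 9 (camera adjusted p = 0.0177). Their value was adjusted p = 0.637 with an estimated correlation, and RT1-Ba and RT1-DMa had log2 differences of -0.17 and -0.16, the former -0.11 without VSG replicate 5. B and plasma cell genes were lower in 16 of 16 (camera adjusted p = 0.019), with list means of 5.31 ± 1.67 against 6.10 ± 1.62. This list had adjusted p = 0.717 with an estimated correlation, and Jchain and Mzb1 had log2 differences of -0.38 and -0.97. With a B and plasma cell covariate the T and NK, macrophage, MHC class II and lipid absorption lists did not pass by camera (adjusted p = 0.155, 0.289, 0.206 and 0.257). With only the arrays low in B cell genes, chosen after the data were seen, the T and NK and macrophage lists passed (0.000468 and 0.000811). The MHC class II and lipid absorption lists did not (0.0885 and 0.129).

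Of the lists after VSG, sugar, peptide and proliferation genes passed by camera with each of the 12 arrays left out in turn. Lipid absorption genes did not pass without Sham_VSG replicate 4 (adjusted p = 0.136), nor clock genes without VSG replicate 6 (adjusted p = 0.0543). Macrophage genes did not pass without VSG replicate 6 or Sham_VSG replicate 2, and T and NK genes without either of these or VSG replicate 3 (adjusted p of at most 0.0860 and 0.0899). MHC class II genes did not pass without VSG replicates 3, 5 or 6 or Sham_VSG replicates 2 or 4 (at most 0.0925). B and plasma cell and posterior Hox genes did not pass without VSG replicates 2, 3, 5 or 6 or Sham_VSG replicates 1, 2 or 4 (at most 0.285 and 0.0946). In the 16 other alternatives the call was lost in 6 for fat cell genes (at most 0.842), in 4 each for lipid absorption, MHC class II and posterior Hox genes (at most 0.672), and lost or turned in 4 for B and plasma cell genes (at most 0.717). For T and NK and macrophage genes it was lost in 3 each, and for the other 4 lists in 2 each (at most 0.657).

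Against Sham_VSG_PF the comparison asked what VSG changed at matched food intake. S100g was again higher, at 10.54 ± 0.55 against 8.56 ± 0.67, which is 3.95-fold and above the sham mean in 6 of 6 arrays, and did not pass (adjusted p = 0.489). The clock gene Per1 was at 6.66 ± 0.40 against 5.87 ± 0.24 (adjusted p = 0.489). Tm4sf5 was at 8.59 ± 0.67 against 7.16 ± 0.85, and Mfsd2a, a lysolipid transporter, at 6.86 ± 0.50 against 5.88 ± 0.50 (both with adjusted p = 0.489). The monocyte receptor Cd14 was at 6.31 ± 0.23 against 6.79 ± 0.17 (adjusted p = 0.558). Slc3a2 and Entrep1 had log2 differences of 0.36 and 0.55, and Ptmal3, Sncaip and Hikeshi of -0.70, -0.51 and -0.37. With limma 0 genes passed, with 649 at an unadjusted p under 0.05. Smooth muscle list means were 7.54 ± 0.24 in VSG and 7.75 ± 0.24 in Sham_VSG_PF arrays. A covariate for these genes, which is not independent of the groups compared, gave 67 genes, 42 higher and 25 lower. S100g was among the higher (log2 difference 2.13, limma adjusted p = 0.0324).

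By camera 12 lists passed against Sham_VSG_PF, with 0 members past the threshold over all genes. Lipid absorption genes were higher in 17 of 20, 1 adjusted over the list alone (camera adjusted p = 9.98e-05). Fatty acid oxidation genes were higher in 18 of 22, 0 adjusted over the list alone (camera adjusted p = 0.000655). Both had adjusted p = 0.441 with an estimated correlation. Creb3l3 and Mttp, of the lipid list, had log2 differences of 0.95 and 0.42. Decr1 and Acaa2, of the oxidation list, had log2 differences of 0.45 and 0.41. Peptide genes were higher in 12 of 14, 1 adjusted over the list alone (camera adjusted p = 0.00244). They had adjusted p = 0.441 with an estimated correlation, and Slc7a8 had a log2 difference of 0.39. Sugar genes were higher in 6 of 8, 1 adjusted over the list alone (camera adjusted p = 0.0406). They had adjusted p = 0.507 with an estimated correlation, and Treh and Pck1 had log2 differences of 0.68 and 0.59, the latter 0.31 without Sham_VSG_PF replicate 5. Bile acid genes were higher in 7 of 11, 0 adjusted over the list alone (camera adjusted p = 0.022). The bile acid list had adjusted p = 0.441 with an estimated correlation. The ileal hormone gene Fgf19, the name the array gives, was at 9.60 ± 2.23 against 7.34 ± 2.16 (adjusted p = 0.833). Nr0b2, another target of the bile acid receptor, was at 7.48 ± 2.30 against 5.50 ± 1.37 (adjusted p = 0.780).

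Immediate early genes were higher against Sham_VSG_PF in 11 of 14, 2 adjusted over the list alone (camera adjusted p = 0.01). They had adjusted p = 0.441 with an estimated correlation, and Fos and Zfp36 had log2 differences of 0.90 and 0.34. Clock genes were higher in 9 of 11, 1 adjusted over the list alone (camera adjusted p = 0.0292). The clock list had adjusted p = 0.441 with an estimated correlation, and Dbp had a log2 difference of 0.61. Proximal genes were higher in 8 of 9 and fat cell genes in 8 of 8, with 0 adjusted over the list alone in both (camera adjusted p = 0.0271 and 0.00801). Each had adjusted p = 0.441 with an estimated correlation. Apoa4 and Onecut2 had log2 differences of 0.45 and 0.22, and Cidec and Lep of 0.43 and 0.38. Lep, at percentile 0.92 of the tested genes by mean level, and Onecut2, at 2.21 in Sham_VSG_PF replicate 4, lay near the filter on dim genes. Without detection calls the sizes of these 2 differences are uncertain. Here too the fat cell list rests on VSG replicate 1, without which it did not pass (camera adjusted p = 0.570), with Lep's difference at 0.16 and Cidec's at 0.27. Cidec's difference was also 0.27 without Sham_VSG_PF replicate 5.

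Smooth muscle genes were lower in VSG than in Sham_VSG_PF in 7 of 9 members, 3 adjusted over the list alone (camera adjusted p = 0.00193). Their list means were 7.54 ± 0.24 in VSG, 7.53 ± 0.18 in Sham_VSG and 7.75 ± 0.24 in Sham_VSG_PF arrays. Of these groups the pair-fed one had the highest mean, and VSG lay near the shams without paired feeding. The means of RYGB and Sham_RYGB, 7.675 ± 0.199 and 7.647 ± 0.207, lay between those of VSG and the pair-fed group. The list had adjusted p = 0.441 with an estimated correlation, and Myl9 and Tagln had log2 differences of -0.40 and -0.34. MHC class II genes were lower in 9 of 9, 0 adjusted over the list alone (camera adjusted p = 0.00801). That list had adjusted p = 0.441 with an estimated correlation, and RT1-DMa and RT1-Ba had log2 differences of -0.27 and -0.19. T and NK genes were lower in 20 of 20, 0 adjusted over the list alone (camera adjusted p = 0.01). Their value was adjusted p = 0.593 with an estimated correlation, and Cd3g and Gzma had log2 differences of -0.32 and -0.89. The B and plasma cell list mean was 5.31 ± 1.67 in VSG and 5.53 ± 1.73 in Sham_VSG_PF arrays, and the fat cell list mean 4.73 ± 1.16 and 4.29 ± 0.22. The iron, hypoxia and hormone lists did not pass against Sham_VSG_PF (camera adjusted p = 0.284, 0.136 and 0.284).

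Of the lists against Sham_VSG_PF, lipid absorption, fatty acid oxidation and MHC class II genes passed by camera with each of the 12 arrays left out in turn. Peptide genes did not pass without Sham_VSG_PF replicate 5 (adjusted p = 0.0767), nor smooth muscle or immediate early genes without VSG replicate 4 (adjusted p = 0.0536 and 0.0531). Proximal genes did not pass without VSG replicate 1 or Sham_VSG_PF replicate 6 (at most 0.215), nor bile acid genes without VSG replicates 2, 3 or 6 or Sham_VSG_PF replicate 5 (at most 0.165). T and NK genes did not pass without VSG replicates 3 or 6 or Sham_VSG_PF replicates 1 or 5 (at most 0.268). Clock genes did not pass without these or VSG replicate 5 (at most 0.136), and sugar genes without these 5 or VSG replicate 1 (at most 0.234). In other alternatives, part of them chosen after the data were seen, the call was lost in 11 of 16 for sugar genes (adjusted p of at most 0.584), 8 of 16 for proximal genes (at most 0.464) and 7 of 16 for fat cell genes (at most 0.836). For each of the other 9 lists it was lost in 2 to 4 of 16 (at most 0.895, for smooth muscle genes).

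Paired feeding alone, Sham_VSG_PF against Sham_VSG, asked what feeding matched to the operated rats changed in sham-operated rats. Smooth muscle genes were higher in 9 of 9 members, 1 adjusted over the list alone (camera adjusted p = 0.000358). The list had adjusted p = 0.915 with an estimated correlation. Myl9 was at 9.90 ± 0.28 against 9.48 ± 0.10, and Actg2 at 11.13 ± 0.17 against 10.79 ± 0.25 (adjusted p = 0.553 and 0.887). Posterior Hox genes were higher in 9 of 9 (camera adjusted p = 0.0327). They had adjusted p = 0.915 with an estimated correlation, and Hoxc8 and Hoxc9 had log2 differences of 0.33 and 0.32, the former 0.21 without Sham_VSG replicate 2. The B and plasma cell list means were 5.53 ± 1.73 in Sham_VSG_PF and 6.10 ± 1.62 in Sham_VSG arrays. In these 2 groups the Hox means lay between 4.22 and 4.42 in the 5 arrays high in B and plasma cell genes and between 4.57 and 4.94 in the other 7. With a B and plasma cell covariate the Hox list did not pass (adjusted p = 0.157), and with only the arrays low in these genes it did (adjusted p = 0.0257). Pancreatic acinar genes were higher in 4 of 4 tested members (camera adjusted p = 0.0327). The list holds 18 symbols, and the others had no cluster of their own or, like Prss1, Cpa1 and Pnlip, fell below the filter on dim genes. The acinar list had adjusted p = 0.298 with an estimated correlation, and Cela2a and Ctrc had log2 differences of 0.32 and 0.24. Fatty acid oxidation genes were lower in 17 of 22 and proliferation genes in 21 of 24 (camera adjusted p = 0.0327 and 0.0326). Each had adjusted p = 0.915 with an estimated correlation. Hadha and Acaa2 had log2 differences of -0.25 and -0.40, and Rrm2 and Kif11 of -0.53 and -0.27. In these last 4 lists 0 members passed over all genes and 0 adjusted over the list alone. Smooth muscle genes passed by camera with each of the 12 arrays left out in turn. Acinar genes did not pass without replicate 4 of either group (adjusted p of at most 0.0957). Fatty acid oxidation genes did not pass without Sham_VSG replicates 1, 3 or 6 or Sham_VSG_PF replicates 1 or 5 (at most 0.148). Proliferation genes did not pass without Sham_VSG replicates 2, 4, 5 or 6 or Sham_VSG_PF replicates 3 or 4 (at most 0.170). Posterior Hox genes did not pass without Sham_VSG replicates 1, 2 or 4 or Sham_VSG_PF replicates 2, 3, 4 or 6 (at most 0.109). In the other alternatives acinar genes lost the call in 7 of 15 and posterior Hox genes in 7 of 16 (at most 0.386 and 0.935). Fatty acid oxidation genes lost it in 5, proliferation genes lost it or turned in 6, and smooth muscle genes lost it in 3 of 16 (at most 0.915).

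With limma 0 genes passed for paired feeding, and the lowest adjusted p was 0.186. There were 582 genes with an unadjusted p under 0.05. Without Sham_VSG_PF replicate 4 the count was 1, and with only the arrays low in B cell genes, an alternative chosen after the data were seen, it was 1. The genes with the smallest p were Tmem269, Or14j5e, Xcl1 and Peds1, with log2 differences of 0.55, 0.65, 0.98 and 0.35. Kctd9, Tmlhe, Lrrc59, Mtpap, Abhd3 and Actg1 had log2 differences of -0.49, -0.78, -0.50, -0.41, -1.46 and -0.24.

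The RYGB effect was set against the VSG effect to ask whether the operations differ. Tfrc differed by a log2 value of 0.86, Lap3 by 0.73 and Cpt1a by 0.67 in favour of RYGB (adjusted p = 0.6249, 0.406 and 0.695). Alox5 differed by -0.99 and Ptprz1 by -0.67 (adjusted p = 0.546 and 0.406). Nqo1, Riok2, Odf2l, Syt17, Hebp2 and Plat, also among the smallest p, differed by 1.37, 0.60, 0.98, 0.82, 0.97 and 1.35. Part of such a difference can lie in the shams, where Sham_RYGB minus Sham_VSG was -0.90 for Nqo1, -0.40 for Riok2 and 0.33 for Alox5. With limma 0 genes passed and 624 had an unadjusted p under 0.05, so the operations were not shown to differ for any named gene. Of the 20 genes that passed after RYGB, 15 had the same sign after VSG. Testing all transcript clusters, chosen after the data were seen, gave 1.

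By camera 6 lists differed between the operations, with 0 members past the threshold over all genes. Fatty acid oxidation genes were higher for RYGB in 18 of 22, 1 adjusted over the list alone (camera adjusted p = 2.12e-05). The oxidation list had adjusted p = 0.547 with an estimated correlation, and Slc25a20 differed by a log2 value of 0.65. Lipid absorption genes were higher in 16 of 20, 0 adjusted over the list alone (camera adjusted p = 0.00203). The lipid list had adjusted p = 0.629 with an estimated correlation, and Apoc2 and Plin2 differed by 0.63 and 0.89. Goblet cell genes were higher in 11 of 13, 0 adjusted over the list alone, and fat cell genes in 8 of 8, 1 adjusted over the list alone (camera adjusted p = 0.0171 for both). Each had adjusted p = 0.629 with an estimated correlation. Spink4 and Zg16 differed by 0.78 and 0.13, and Cidec and Car3 by 1.12 and 1.78. The Car3 value was 1.06 without RYGB replicate 1 and 2.73 without VSG replicate 1. Tuft cell genes were lower in 11 of 12, 2 adjusted over the list alone, and stem cell genes in 8 of 9, 0 adjusted over the list alone (camera adjusted p = 1.37e-05 and 0.0171). Each had adjusted p = 0.152 with an estimated correlation. Pou2f3 differed by -1.20, and Ascl2 and Lgr5 by -0.59 and -0.63. For 2 of these lists the shams differed too, in the opposite direction: fatty acid oxidation means were 6.76 ± 0.31 in Sham_RYGB and 6.91 ± 0.14 in Sham_VSG arrays (camera adjusted p = 0.0066), and tuft cell means 4.95 ± 0.33 and 4.76 ± 0.15 (camera adjusted p = 0.0113). These 2 had adjusted p = 0.905 with an estimated correlation. Of the 24 arrays left out in turn, Sham_RYGB replicate 3 ended the difference for lipid absorption genes (adjusted p = 0.0850). For goblet cell genes it ended without that array, RYGB replicate 5, VSG replicates 4 or 6 or Sham_VSG replicates 3 or 6 (at most 0.0887). For fat cell genes it ended without RYGB replicates 1, 3 or 6 or VSG replicates 2 or 6 (at most 0.113). In the 16 other alternatives the difference was lost in 2 to 4 for each list other than fat cells, and lost or turned in 5 for fat cells (at most 0.794).

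Across the 10918 genes, which are not independent replicates, the log2 fold changes of VSG and RYGB had a correlation of 0.416 (Spearman 0.327), with 0 shared calls. Of 100 regroupings of the arrays, 18 gave a correlation as large in size. With a B and plasma cell covariate, chosen for this after the data were seen, it was 0.0763. The VSG and paired feeding effects, which share the Sham_VSG arrays, had a correlation of 0.560 (Spearman 0.516). Simulated groups with no effect gave 0.498, and setting each effect against a different 3 of the 6 shams gave 0.0654 on average.

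The sham groups of the operations, Sham_RYGB against Sham_VSG, were compared to see how far they differ. By camera 6 lists passed, each with 0 members past the threshold over all genes and 0 adjusted over the list alone. Fatty acid oxidation genes were lower in Sham_RYGB in 19 of 22 members (camera adjusted p = 0.0066). Proliferation genes were lower in 23 of 24 and T and NK genes in 20 of 20 (camera adjusted p = 0.0113 for both). All 3 lists had adjusted p = 0.905 with an estimated correlation. Eci1 and Hadha had log2 differences of -0.33 and -0.23, Kif11 and Plk1 of -0.28, and Klrd1 and Cd7 of -0.34 and -0.42, the last 2 at -0.17 without Sham_VSG replicate 4 and -0.27 without Sham_VSG replicate 5. Tuft cell genes were higher in 10 of 12, smooth muscle in 8 of 9 and fibroblast genes in 15 of 19 (camera adjusted p = 0.0113, 0.0331 and 0.0331). These lists too had adjusted p = 0.905 with an estimated correlation. Il17rb and Alox5 had log2 differences of 0.49 and 0.33, Actg2 and Myl9 of 0.23 and 0.15, and Col4a2 and Col6a1 of 0.25 and 0.21. Il17rb was at 0.29 without Sham_RYGB replicate 5, and Actg2 at 0.14 without Sham_VSG replicate 2. With limma 0 genes passed and 514 had an unadjusted p under 0.05. Or14j5e, Zfp709l1, Schip1 and E4f1, not past the threshold, had log2 differences of 0.81, 0.56, 0.46 and 0.64. Nudt2, Swi5, Nqo1, Kpna2l1, Riok2 and Tmlhe, also not past it, had -0.41, -0.50, -0.90, -0.61, -0.40 and -0.70.

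The lists that passed in no comparison are given by their medians after RYGB and after VSG, each against its own shams. Cholesterol synthesis genes had medians of -0.02 and -0.08 (camera adjusted p = 0.807 and 0.257), Paneth cell genes -0.01 and 0.00 (camera adjusted p = 0.854 and 0.207), epithelial defence genes 0.08 and -0.35 (camera adjusted p = 0.624 and 0.0662), and mast cell and eosinophil genes -0.13 and -0.08 (camera adjusted p = 0.239 and 0.803). Interferon response genes had medians of -0.11 and 0.06 (camera adjusted p = 0.148 and 0.421), enteric neuron and glia genes -0.06 and 0.09 (camera adjusted p = 0.408 and 0.315), and red blood cell genes 0.15 and 0.49 (camera adjusted p = 0.807 and 0.0906). Xenobiotic and glutathione genes had medians of 0.10 and 0.04 (camera adjusted p = 0.0957 and 0.643), and genes of the unfolded protein and integrated stress response 0.05 and 0.03 (camera adjusted p = 0.239 and 0.166). The direction of the test was opposite to the sign of the median after RYGB for the cholesterol, bile acid (median 0.07, camera adjusted p = 0.812) and posterior Hox lists, and after VSG for the iron, hormone and goblet cell lists, none of which passed there.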

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

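The tests on the split of the B and plasma cell list, on lymphoid content and on the share of each fold change kept with a fat cell covariate or without the arrays high in fat cell genes were chosen after the results were seen. So were the checks in only the arrays low in B cell or fat cell genes, that of Cidec among them. The weighing of the proximal, bile acid and posterior Hox lists and of Fgf19 was also chosen then. The other tests in this part were fixed before their results were seen.

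The B and plasma cell list parted the arrays into a lower set of 19 and an upper set of 11. Lymphoid follicle tissue in some pieces of ileum may account for this. Outside the list, 9 markers of lymphoid follicles had a median difference of 2.45 on the log2 scale. Glycam1 was at 9.75 ± 0.73 against 2.70 ± 0.76 and Ccl19 at 9.50 ± 0.58 against 3.29 ± 0.49 (mean ± SD of the upper against the lower set). Ltb, Il21r and Cd83, with differences of 2.45, 2.16 and 1.90, are genes of immune cells and not of follicle stroma or high endothelium alone. The operation is excluded as the sole cause of the split, since 8 of the 18 sham arrays lay in the upper set. Of the 12 arrays of operated rats 3 lay there, so an effect of the operation on lymphoid content is not excluded. The number of follicles in each piece was not recorded in the labels, so the account by follicle tissue stays a hypothesis.

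The 20 genes past the threshold after RYGB were set against tissue carried along with the pieces. Lower lymphoid content is argued against as the whole cause, since 17 of the 20 passed with the B and plasma cell covariate. Alox5, Tmem150b and Lpgat1 did not (limma adjusted p = 0.0702, 0.0702 and 0.0564), with Alox5 at a log2 difference of -0.74 in place of -0.78. With only the arrays low in B cell genes (5 against 3) 7 of the 20 passed, and all 20 kept a median 0.924 of their log2 fold change. Fat cells, whose genes were high in 3 of the 6 RYGB arrays and in 0 of the 6 Sham_RYGB arrays, cannot be told apart as a cause of the calls, of which 2 of 20 passed with a covariate of the fat cell genes other than Cidec and by limma 0 without the high arrays (20 at an unadjusted p under 0.05). Nor can they be told apart as a cause of part of the fold changes: with the covariate, which raised the median SE 1.12 times, the genes kept a median 0.955 and at least 0.835 of these, and without the high arrays a median 0.942 and at least 0.597, where Tfrc went from 0.82 with an SE of 0.15 to 0.72 with an SE of 0.17 and to 0.49 with an SE of 0.16 (95% interval 0.16 to 0.81). Fat cells are argued against as the whole cause for Cidec, which kept a log2 fold change of 1.43 (95% interval 0.90 to 1.97; adjusted p = 0.0396) of 1.70 with the covariate and whose lowest value in the 3 RYGB arrays low in fat cell genes, 7.70, lay above the highest Sham_RYGB value, 6.92, so an effect of the bypass on Cidec remains a hypothesis.

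The higher lipid absorption and fatty acid oxidation lists after RYGB were set against a different make-up of the pieces. A more proximal piece of gut cannot be told apart. The ileal genes Slc10a2, Fabp6, Slc51a and Slc51b changed by 0.0627 on average on the log2 scale (95% interval -0.12 to 0.25) and so met the bound fixed beforehand against it, an interval above -0.5, but that bound rested on no measured value, since no array of another stretch of gut shows how steeply these genes fall along it. The proximal list, higher in 8 of 9 members (camera adjusted p = 0.00682, and adjusted p = 0.166 with an estimated correlation), and Fgf19, at 5.15 ± 1.61 against 9.21 ± 1.98 (adjusted p = 0.134), go with it. That list shares Fabp1 and Apoa4 with the lipid absorption list, so it is not independent of the pattern. Fgf19 is a target of the bile acid receptor and need not mark a place along the gut. The bile acid list had 8 of 11 members higher (median 0.07, camera adjusted p = 0.812) with a lower list mean (7.10 ± 0.27 against 7.61 ± 0.37). The posterior Hox list mean was not lower (4.72 ± 0.26 against 4.65 ± 0.23). Hox means were lower in arrays high in B and plasma cell genes, which were 1 RYGB and 3 Sham_RYGB. In the others they lay between 4.66 and 4.96 in RYGB and 4.80 and 4.88 in Sham_RYGB, so the Hox list does not decide. A larger share of epithelium cannot be told apart either. The 16 epithelial markers were at 9.92 ± 0.07 against 9.75 ± 0.18. The mean of the lipid absorption and fatty acid oxidation lists minus theirs was higher after RYGB by 0.22 (exact permutation p = 0.0563). The mean of both lists alone differed by 0.38 (exact permutation p = 0.0238, n = 6 per group).

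Arrays far from the other 5 of their group were sought in 345 groups of gene values and 165 groups of list means, where chance gives 1 in 20; 32 and 10 were found. Each is given by its gap to the nearest array as a share of the group's range, above Dixon's 95% critical value for 6 arrays. VSG replicate 1 was highest for the fat cell list (0.968), the proximal list (0.690), the tuft cell list (0.655), Car3 (0.897) and Retn (0.770). VSG replicate 4 was lowest for the lipid absorption list (0.6251), the peptide list (0.638), Mttp (0.699), Slc5a1 (0.774) and Zg16 (0.654). RYGB replicate 4 was highest for the B and plasma cell list (0.929), Cd180 (0.891) and Pou2af1 (0.658) and lowest for the clock list (0.651). VSG replicate 5 was lowest for Fgf19 (0.649) and Nr0b2 (0.664) and highest for Nqo1 (0.661). Sham_RYGB replicate 3 was lowest for Ada (0.804), Apoa4 (0.643) and Areg (0.75). Sham_VSG_PF replicate 5 was lowest for Actg2 (0.722) and Tagln (0.681) and highest for Or14j5e (0.633). RYGB replicate 5 was highest for the iron genes Cybrd1 (0.719) and Slc40a1 (0.641). Sham_VSG_PF replicate 4 was highest for S100g (0.637) and lowest for Onecut2 (0.713).

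Sham_VSG replicate 6 was lowest for the tuft cell list (0.705) and Il17rb (0.711), and Sham_VSG replicate 2 lowest for the xenobiotic list (0.634) and highest for RT1-DMa (0.634). Slc25a20 was highest in RYGB replicate 6 (0.635) and lowest in Sham_VSG replicate 4 (0.644). In the VSG group, replicate 2 was lowest for the hypoxia list (0.666), replicate 3 for Hebp2 (0.635) and replicate 6 for Apoc2 (0.854). In the Sham_VSG group, replicate 1 was lowest for Plk1 (0.65), replicate 5 for Cela2a (0.657), and replicate 3 highest for Zg16 (0.677). RYGB replicate 2 was lowest for Ccl2 (0.660), Sham_RYGB replicate 2 highest for Ptprz1 (0.748), and Sham_VSG_PF replicate 6 highest for Xcl1 (0.726).

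The effects of RYGB and VSG differed by camera's test of the difference, at the preset correlation, for the lipid absorption (adjusted p = 0.00203), fatty acid oxidation (adjusted p = 2.12e-05), goblet cell (adjusted p = 0.0171) and fat cell (adjusted p = 0.0171) lists, higher for RYGB, and the tuft cell (adjusted p = 1.37e-05) and stem cell (adjusted p = 0.0171) lists, lower for RYGB. With an estimated correlation 0 of these 6 lists passed.

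Among the 14573 clusters that carry no gene symbol, tested above only in the alternative with all transcript clusters, transcript cluster 17882751 was higher after RYGB by 1.12 on the log2 scale (8.84 ± 0.39 against 7.72 ± 0.13, n = 6; limma adjusted p = 0.000304 over 27514 clusters). Its RYGB effect exceeded its VSG effect by 1.21 (adjusted p = 0.036), with a VSG effect of -0.09.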

How the results depend on the processing

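Alternatives using fat cell genes, arrays low in B cell genes or all transcript clusters, and the overlaps with a B and plasma cell covariate, were chosen after seeing the data. After RYGB 20 genes passed (17 higher, 3 lower); quantile normalization, median centring, either filter, quality weights, a variance trend, cluster means, the B and plasma cell covariate and a 1.5-fold minimum gave 15 to 25, with 20 higher and 1 lower after centring. With the replicate number as a block, 18 passed, 16 of them shared. Of the genes named by the rule Aqp3 and Alox5 did not pass (limma adjusted p = 0.0511 and 0.0634), and the other calls lost were among the genes named outside the rule. The sugar list against Sham_VSG_PF did not pass (camera adjusted p = 0.0602), and no other call of a list or of a gene named by the rule changed. The labels do not say that the numbers pair rats: deviations from the group mean correlated over 0.1 in 5 of 6 same-numbered pairs for VSG and Sham_VSG (mean 0.312, other numbers -0.0599), 2 for RYGB and Sham_RYGB (-0.0829, 0.0181), 4 for VSG and Sham_VSG_PF (0.0449, 0.00212) and 3 for the VSG sham groups (-0.0283, 0.00817), with 3, 0, 2 and 1 of 6 arrays closest to their own number. The first principal component of the arrays had a correlation of 0.988 with the B and plasma cell list. The arrays high in that list were VSG replicates 1 and 4, Sham_VSG replicates 1, 2 and 4 and Sham_VSG_PF replicates 1 and 5. In the bypass groups they were RYGB replicate 4 and Sham_RYGB replicates 1, 2 and 3. The correlations of same-numbered arrays therefore do not tell pairing of rats from shared lymphoid content. Fitting only the groups compared gave 0 for RYGB, with 10 residual degrees of freedom in place of 25. A smooth muscle covariate gave 67 for RYGB and 67 for VSG against Sham_VSG_PF. An adjusted p below 0.10 gave 44, by construction, the fat cell covariate 1, arrays low in B cell genes 8 (5 against 3 arrays), leaving out arrays high in fat cell genes 1 (3 against 6 arrays), and all clusters 3, with more features tested. Leaving out 1 array gave 2 to 41: 10 without RYGB replicate 2, 41 without RYGB replicate 4, 2 without RYGB replicate 6, 12, 8 and 3 without Sham_RYGB replicates 1, 2 and 3. For paired feeding it gave 0 to 1 (1 without Sham_VSG_PF replicate 4), and arrays low in B cell genes gave 1 (Tmlhe). For the RYGB effect minus the VSG effect all clusters gave 1. VSG against Sham_VSG and the sham groups gave 0 in all alternatives.

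The iron list after RYGB passed with the median filter (adjusted p = 0.0389), quality weights (0.0486), the B and plasma cell covariate (0.0113), fry (0.0214), arrays low in B cell genes (0.0137) and without arrays high in fat cell genes (0.0213). Leaving out 1 array gave 0.0371 to 0.221: it passed without RYGB replicate 3 (0.0424) and Sham_RYGB replicates 1 (0.0371) and 3 (0.0446). Lists turned direction where the covariate is made of them: B and plasma cells in VSG (0.567) and RYGB (0.896) with their own covariate, and fat cells in RYGB (0.798) and in the RYGB effect minus the VSG effect (0.794) with theirs. B and plasma cells also turned in RYGB with arrays low in them (0.907), and proliferation in paired feeding with a smooth muscle covariate (0.830). The correlation of VSG and RYGB effects was 0.487 with the median filter and 0.0763 with the B and plasma cell covariate; that of VSG and paired feeding was 0.427 with that covariate and 0.0654 with split shams, where the shared arrays no longer enter both effects. Except where stated, the cause was not tested. Among other list results 572 held, 157 were lost and 6 turned; among named genes 2351 held, 59 were lost and 17 gained a call. Leaving out 1 array, 537 list results held and 87 were lost; among named genes 2295 held, 60 were lost and 9 gained a call. The acinar cell list had no genes under the median filter. Precision is limited by 6 rats per group.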

Other observations

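The test on vitamin D target genes and the counts over other splits of the arrays were fixed before their results were seen. The exact permutation test of those target genes, the splits' counts at an unadjusted p and their correlation with the B and plasma cell list were added afterwards, and the decision on the target genes stays with the test fixed first.

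With smooth muscle genes as a covariate, 67 genes differed between VSG and Sham_VSG_PF, 42 higher and 25 lower. The covariate itself differed between these groups (list means of 7.54 ± 0.24 and 7.75 ± 0.24), so it is not independent of the comparison. The genes named here were chosen after their values were seen. Beside S100g (log2 difference 2.13; adjusted p = 0.0324) they included the manganese exporter Slc30a10 (1.81; adjusted p = 0.0132), Tm4sf5 (1.60; adjusted p = 0.036), the lipid genes Creb3l3 (1.14; adjusted p = 0.0435) and Mttp (0.60; adjusted p = 0.0296), the clock gene Per1 (0.93; adjusted p = 0.0213) and Fos (1.23; adjusted p = 0.0213). The lower ones included Mzb1 of the B and plasma cell list (-1.66; adjusted p = 0.0213), Aif1 and Cd14 of the macrophage list (-0.68 and -0.59; adjusted p = 0.0481 and 0.0213), Cd3g of the T and NK list (-0.48; adjusted p = 0.0435), and Ccl17 and Bcl2a1, which are in none of the lists (-1.25 and -1.22; both with adjusted p = 0.0296). Without the covariate 0 genes passed by limma and 649 had an unadjusted p under 0.05.

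S100g was 3.35-fold higher in VSG than in Sham_VSG and 3.95-fold higher than in Sham_VSG_PF, short of the threshold in both (adjusted p = 0.605 and 0.489). A rise of vitamin D target genes as a group might account for it and could not be decided. For 6 other targets, with median log2 differences of 0.08 against Sham_VSG and 0.17 against Sham_VSG_PF, camera gave p = 0.0622 and 0.0416, where an exact permutation test of their mean over 924 splits gave p = 0.364 and 0.262. Among them Cyp24a1, the most direct target, had log2 differences of -0.01 and 0.22.

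The arrays of each comparison were regrouped at random into groups of the same sizes, 100 splits in each case with the real one included. For the count of 20 genes of RYGB against Sham_RYGB 1 split, the real one, gave as many and the highest other gave 3. With 100 splits the share cannot fall below 1 in 100, so chance is argued against for this count but not excluded. For the 67 genes of VSG against Sham_VSG_PF with the smooth muscle covariate 1 split gave as many and the highest other gave 1. That setting was picked from many alternatives, which the splits do not allow for, so chance is not excluded there either. The splits say nothing about the counts of 0 genes, since every split, 100 of 100, has at least 0; the highest other counts were 1 for VSG against Sham_VSG, 1 for VSG against Sham_VSG_PF, 10 for paired feeding, 1 for the sham groups and 1407 for the RYGB effect minus the VSG effect. The split with 1407 genes points to a structure of the samples: it set the B and plasma cell list apart by 3.86, against -0.42 in the real groups and less in each other split. Over the 99 other splits the size of that contrast and the number of genes at an unadjusted p under 0.05 had a Spearman correlation of 0.644. Nor can chance be excluded for the number of lists past the threshold at the preset correlation: 24 of 100 splits gave as many as the 11 of VSG against Sham_VSG (highest other 20), 24 as many as the 12 of RYGB (16), 27 as many as the 12 of VSG against Sham_VSG_PF (17), 45 as many as the 5 of paired feeding (18) and 56 as many as the 6 of the RYGB effect minus the VSG effect (18). The same holds for the numbers of genes at an unadjusted p under 0.05, since the genes are correlated: 5 of 100 splits gave as many as the 1414 of RYGB (highest other 2302), 15 as many as the 661 of VSG against Sham_VSG (1831), 26 as many as the 649 of VSG against Sham_VSG_PF (2056), 27 as many as the 582 of paired feeding (2375), 14 as many as the 624 of the RYGB effect minus the VSG effect (3206) and 31 as many as the 514 of the sham groups (2090).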
